A study of Candidatus Epulonipiscium viviparus with 7 samples.

How the data were processed

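RNA was sequenced from cells of 'Candidatus Epulopiscium viviparus' taken out of the guts of 7 Naso tonganus, 1 library per fish. Per the labels, fish were caught by spear, kept on ice and dissected, and RNA was extracted with an RNeasy kit from every sample except evening replicate 2, which was extracted with Trizol. Per the labels, each sample came from a different fish, so the spread between libraries of 1 group is a spread between animals. Groups were taken from the catch time in the labels: 2 early morning, 3 mid morning and 2 evening libraries. The labels number no replicates, so numbers were given in accession order and pair no samples.

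The authors deposited 1 table of FPKM values (fragments scaled to gene length and to mapped fragments) for 2796 genes. It gives gene names and products and a column for each of the 7 samples. An annotation sheet of 2883 features came with it. Coding lengths were computed here from the protein translations in that sheet, with a stop codon added. No value columns of other samples were present. The annotation sheet held 87 features that had no FPKM values, among them 18 rRNA and 54 tRNA features. Reads were trimmed with Trimmomatic 0.36 and aligned with BWA, as far as the tool names in the submitters' processing notes show. The BWA version, the genome build, the program that computed the deposited FPKM, the strand setting and the treatment of reads shared by similar genes were not given in the sources used here. Gene names, products and identifiers are those of the deposited table, and genomic coordinates were not used here.

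The deposited FPKM columns were of 2 kinds. In early morning replicate 2 and evening replicate 2 the values had 2 decimals, and each low value multiplied by the coding length was a whole multiple of 1 step. Within 0.1 of a step, 100% of the 296 low values of the first library and 100% of the 30 of the second were whole. The steps correspond to 3.32e+06 and 5.70e+07 reads. The other 5 columns had 6 significant digits and no such step (36.0% to 46.3% of low values whole within the same tolerance), so their depth is unknown, and counting error could be given for no value in them. They also listed more genes at 0, between 91 and 125 against 43 and 3. A 0 in these files can be a failed estimate, and a gene is therefore only said to be listed at 0. The values are not counts, and no count model was used.

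From the deposited FPKM, log2(FPKM + 1) was computed. A fold change is on that scale, which understates the change of genes with low values. Genes with a mean FPKM of at least 1 over the 7 libraries were tested (2758 of 2796). limma 3.58.1 in R 4.3.3 was fitted to all 7 libraries with a mean per time of day and no covariate, with a trend in the prior variance. The residual degrees of freedom were 4 and the prior added 3.47. A moderated F test over the 3 times and 3 pairwise contrasts were made, each adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Every adjusted p given for a gene is from limma. Errors of log2 differences are limma standard errors (SE), and errors of FPKM are standard deviations (SD).

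Gene lists were patterns on the product names, written before the data were examined. They covered ribosomal proteins, translation factors and aminoacyl-tRNA synthetases, RNA polymerase and sigma factors, the flagellum, chemotaxis, sporulation and germination, cell division, DNA replication, peptidoglycan, ATP synthases, the Rnf complex, sodium carriers, the phosphotransferase system (PTS), ABC sugar transport, glycoside hydrolases, glycolysis, pyruvate conversion and fermentation, amino acid synthesis, nitrogen, nucleotides, fatty acids, chaperones and proteases, redox defence, DNA repair, mobile elements and stable RNA. The 24 lists with at least 5 tested genes were tested with camera from limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. camera compares a list with all other genes. It was repeated with a correlation estimated per list, and fry was run beside it. fry asks whether the genes of a list move 1 way on balance, and compares them with no other genes. Counts of called genes are given over all genes tested and adjusted over the list alone. The share of the summed FPKM held by each list was compared between the 3 times by an exact permutation test over all 105 assignments of the libraries to groups, using the between-group sum of squares.

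Named genes were chosen by a rule written before the data were examined. For each contrast it takes the 10 largest rises and 10 largest falls among annotated genes past the threshold whose groups did not overlap and whose higher group mean was at least 10 FPKM. Where no gene passes, it takes the 5 annotated genes of each direction with the smallest unadjusted p. It adds the 3 members of each list with the smallest p in the F test, the 15 annotated genes with the highest mean FPKM, ftsZ, dnaA, spo0A, the sporulation sigma factors, the most abundant flagellin and the most abundant ATP synthase subunit, and any gene of unknown function among the 5 most abundant. It gave 123 genes, 16 of them by more than 1 part. Genes named outside the rule are said to have been chosen after their values were seen.

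The fit was tested on simulated data with the spread of the real libraries, with 2758 genes, 200 of them changed, in 20 simulations per comparison. The simulated genes varied independently of each other, so the false shares that follow need not hold for correlated genes. For evening against early morning, 1.1% of genes changed by 1 on the log2 scale were recovered, 15.0% at 2, 56.0% at 3 and 79.8% at 4, with 5.89% of the calls false. For mid morning against early morning the shares at 1, 2, 3 and 4 were 2.0%, 23.4%, 68.0% and 85.3%, with 5.75% false. For evening against mid morning they were 2.2%, 23.4%, 69.1% and 86.4%, with 5.18% false. In 100 draws of unchanged groups that kept the real correlation between genes, the median number of genes called was 0 for each comparison, and 4 or 5 draws called any. Those draws called up to 985 genes, since correlated genes pass together. As many as the real count were called in 2 draws for the F test, 5 for mid morning against early morning and 1 for evening against early morning. camera called a median of 3 and at most 7 lists in these draws, against 8, 11 and 9 in the data.

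Alternatives fixed before the data were examined were a pseudocount of 0.1 or 10, no filter or a mean of at least 10 FPKM, median-of-ratios scaling, rescaling of each column to an equal sum, quantile normalization, library weights, no trend, a minimum absolute log2 difference of 1, fits with only the 2 groups compared, and fits without each library in turn. Chosen after the values were seen were a term for the kind of FPKM column, with and without median-of-ratios scaling, fits without both 2-decimal libraries, fits of genes with a coding length of at least 600 nt, and lists from the authors' own carbohydrate-active enzyme labels. Tables were handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.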

Results

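'Candidatus Epulopiscium viviparus' is a very large gut bacterium of the surgeonfish Naso tonganus that forms its offspring inside the mother cell. Its transcript levels were compared between fish taken in the early morning (2 fish), the mid morning (3 fish) and the evening (2 fish), to follow the expression profile through the daily cycle. Expression values (FPKM) were given for 2796 genes with coding lengths of 63 to 20610 nt, of which 1510 (54%) were annotated as of unknown function. Median FPKM per library ran from 67.0 to 108, and the 10 most abundant genes held 17.1% to 32.4% of the summed FPKM. The column sums ran from 828386 in early morning replicate 2 to 2.59e+06 in early morning replicate 1, and the main fit did not rescale them. The low values of early morning replicate 2 and evening replicate 2 implied 3.32e+06 and 5.70e+07 reads, and the depth of the other 5 libraries, whose columns were written in another number format, is unknown.

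Over the 7 libraries rpmH (gene30122), ribosomal protein L34, averaged 94772 ± 81691 FPKM (SD, n = 7), and cspD (gene30046), a cold-shock RNA chaperone, 80974 ± 35031 FPKM. Also among the most abundant were rpsU (gene10179), ribosomal protein S21, at 49712 ± 27901 FPKM, spoIIID (gene10378), a sporulation regulator, at 38688 ± 22773 FPKM, gene70321, of unknown function, at 36424 ± 51557 FPKM, and the six-cysteine peptide SCIFF (gene10333) at 23440 ± 19790 FPKM. Among the most abundant genes, 2 means fell more than 1.5-fold without 1 library: that of gene70321 was 17506 FPKM without evening replicate 1, and that of rpmEA (gene30040), 19439 FPKM over all libraries, was 9703 FPKM without early morning replicate 1. Ribosomal proteins made up 6 of the 15 most abundant annotated genes, with rpmEA, rpmB, rpsO and rpsR beside rpmH and rpsU. The others were a disulfide oxidoreductase (gene40119), phosphoenolpyruvate carboxykinase (gene40109), which joins the citrate cycle to gluconeogenesis, at 17238 ± 13705 FPKM, the sporulation regulator spoVG, the DNA-binding protein hbs, pyruvate formate lyase (pflB) at 9570 ± 7038 FPKM and glyceraldehyde-3-phosphate dehydrogenase (gapA) at 9306 ± 2518 FPKM. As a list, the 50 ribosomal proteins held 19.8 ± 4.27% of the summed FPKM (SD, n = 7).

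Levels of short genes differed between the 2 kinds of FPKM column within a time of day. Genes of up to 200 nt had a median that was 1.44 (log2) higher in the 6-digit than in the 2-decimal library of the early morning, and 0.96 higher in the evening. For genes over 1000 nt the same differences were 0.35 and 0.15. rpmH (135 nt) stood at 252984 and 6939 FPKM in the 2 early morning libraries and at 113145 and 14125 FPKM in the 2 evening libraries. The SD of short genes holds this difference as well as that between fish. Their means over the 7 libraries hold it too, so the order of the most abundant genes rests mostly on the 6-digit columns. In the 2-decimal libraries rpmH was not the most abundant gene, as the highest FPKM was 29403 in the early morning and 51322 in the evening.

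**Figure D1:**
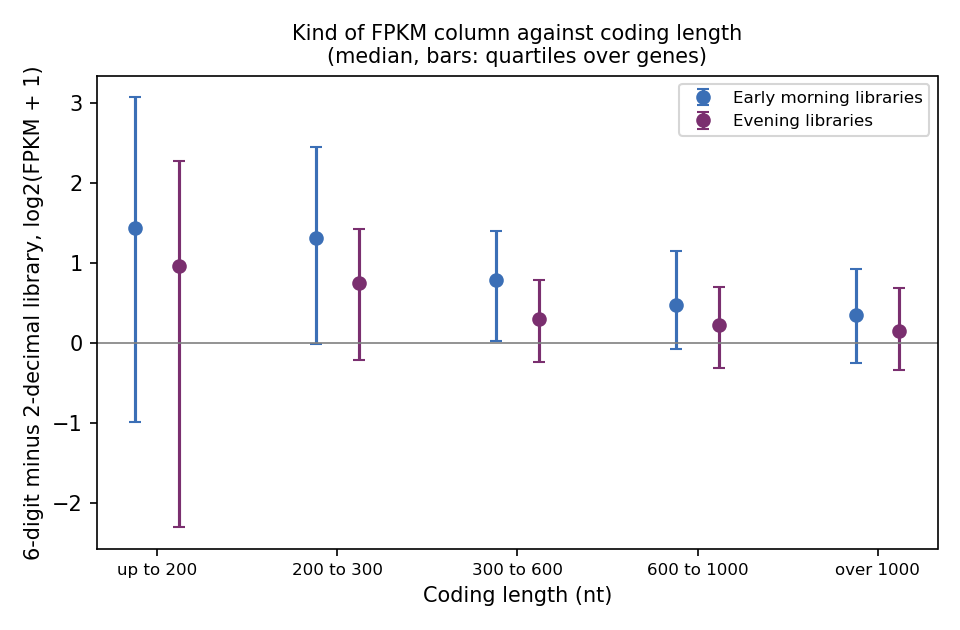
Difference in log2(FPKM + 1) between the 6-digit and the 2-decimal library of the same time of day, by coding length class in nt; points are medians over genes and bars run between the quartiles. The median fell from 1.44 (early morning, up to 200 nt) to 0.35 over 1000 nt, and from 0.96 to 0.15 in the evening.

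Libraries were ordered by time of day along the first principal component of log2(FPKM + 1), which held 43.4% of the variance. The early morning libraries stood at −58.8 and −39.0, the mid morning libraries at −11.9, −11.7 and 20.1, and the evening libraries at 63.5 and 38.0 (exact permutation test of the 3 groups, p = 0.019, smallest possible p 0.0095). The second component (28.3%) parted the 2 libraries with 2-decimal columns from the other 5 and not the times of day (exact permutation p = 0.305). Across genes, which are not independent replicates, libraries of 1 group correlated with r of 0.83 to 0.93, early morning with evening libraries with 0.59 to 0.74, early with mid morning with 0.75 to 0.89 and mid morning with evening with 0.75 to 0.88. Some correlations between groups were thus above those within a group: early morning replicate 1 had 0.89 with mid morning replicate 1 and 0.83 with early morning replicate 2, and evening replicate 1 had 0.88 with mid morning replicate 3 and 0.84 with evening replicate 2. Of 2758 genes tested, 170 differed over the 3 times of day (limma F test, 869 at an unadjusted p under 0.05). The count was 0 without early morning replicate 1, early morning replicate 2, mid morning replicate 1 or evening replicate 1, 51 without evening replicate 2 and 64 without mid morning replicate 2. It was also 0 without both 2-decimal libraries, and 272, 325 and 371 with median-of-ratios scaling, quantile normalization and genes of at least 600 nt.

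**Figure D2:**
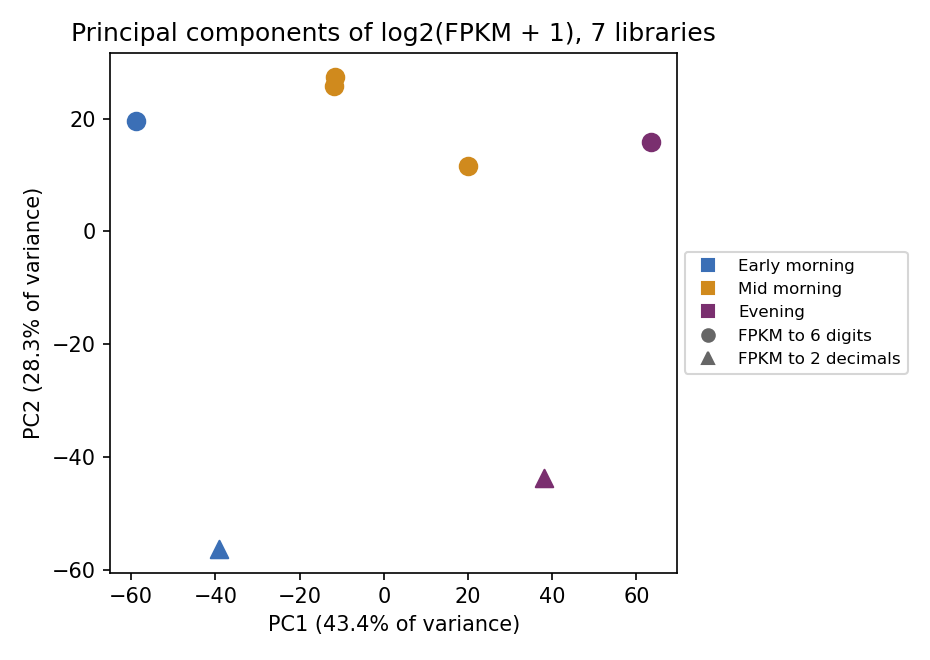
First and second principal components of log2(FPKM + 1) of the 7 libraries, with the share of variance on each axis; color gives the time of day and shape the kind of FPKM column. Early morning libraries lie at −58.8 and −39.0 on the first axis and evening libraries at 38.0 and 63.5, and the 2-decimal libraries lie at −56.3 and −43.8 on the second.

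In the evening, transcripts of amino acid and fatty acid synthesis, translation and the flagellum stood higher than in the early morning, and transcripts of ATP synthases, sugar uptake, sodium carriers and chemotaxis lower. These list calls hold at a preset correlation between genes, and none remained with an estimated one (smallest adjusted p = 0.596). Of the 2758 genes, 342 rose and 194 fell in the evening (limma, 1042 at an unadjusted p under 0.05), among them 126 risen and 103 fallen genes of unknown function. The groups did not overlap for any of the 536, as for 65.8% of all genes, where chance gives 33.3%. Glucose-6-phosphate isomerase (pgi, gene40111), which links glucose-6-phosphate to fructose-6-phosphate, rose from 70.8 ± 7.88 to 3974 ± 297 FPKM (SD, n = 2 each), a log2 difference of 5.79 ± 0.54 (SE, limma adjusted p = 0.0089). Glycerol kinase (glpK, gene60144) fell from 627 ± 277 to 24.2 ± 3.22 FPKM (SD, n = 2 each), a difference of −4.57 ± 0.69 (limma adjusted p = 0.011). The count was 0 without evening replicate 1, 130 (115 higher, 15 lower) without early morning replicate 1, 369 (154 higher, 215 lower) without early morning replicate 2, 246 without mid morning replicate 1, 280 without evening replicate 2 (the Trizol library), 0 without both 2-decimal libraries, 59 with only the 2 groups in the fit and 355 with library weights. All 536 kept their direction in each of these fits, which was fixed beforehand, since their groups did not overlap. Other scalings moved the balance, to 360 higher and 293 lower with median-of-ratios scaling, 209 and 189 with an equal sum and 372 and 366 with quantile normalization. Still called of the 536 were 519, 334 and 521, in the same order. The median log2 difference of all genes, 0.13, shifted by −0.13, −0.24 and −0.21.

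The 10 largest rises included 4 genes of a urea transporter. The urea ABC transporter binding protein (gene60406) rose from 4.69 ± 5.22 to 346 ± 273 FPKM (n = 2 each), by 6.05 ± 1.06 (limma adjusted p = 0.016), and its permeases UrtB (gene60407) and UrtC (gene60408) and ATPase UrtE (gene60410) rose by 5.86, 5.85 and 5.69. An alpha-type small acid-soluble spore protein (gene10416), of the class that coats spore DNA, rose by 6.31 ± 1.47 (limma adjusted p = 0.029). It stood at 175 and 25.5 FPKM in the early morning and 24513 and 1190 FPKM in the evening, and at 165 nt is among the short genes. A sulfatase (gene70239) rose by 6.12 ± 0.82 (limma adjusted p = 0.0095), a GlcNAc-PI de-N-acetylase of family CE14 (gene30290) by 6.02, a collagen triple helix repeat protein fragment (gene20024) by 5.996, and O-acetylhomoserine aminocarboxypropyltransferase (gene60302), a methionine synthesis enzyme that fixes sulfide, by 5.77. The largest falls besides glpK were those of a putative beta-lactamase (gene10355, −4.72), an amino acid permease (gene10022, −4.19), the mannosylglycerate PTS enzyme mngA (gene40411, −4.05), the citrate lyase subunit citE (gene10084, −3.99) and 5 genes of the ATP synthase. Phosphoenolpyruvate carboxykinase (gene40109) fell from 36009 ± 9342 to 6509 ± 1243 FPKM (n = 2 each), by −2.46 ± 0.58 (limma adjusted p = 0.029).

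**Figure D3:**
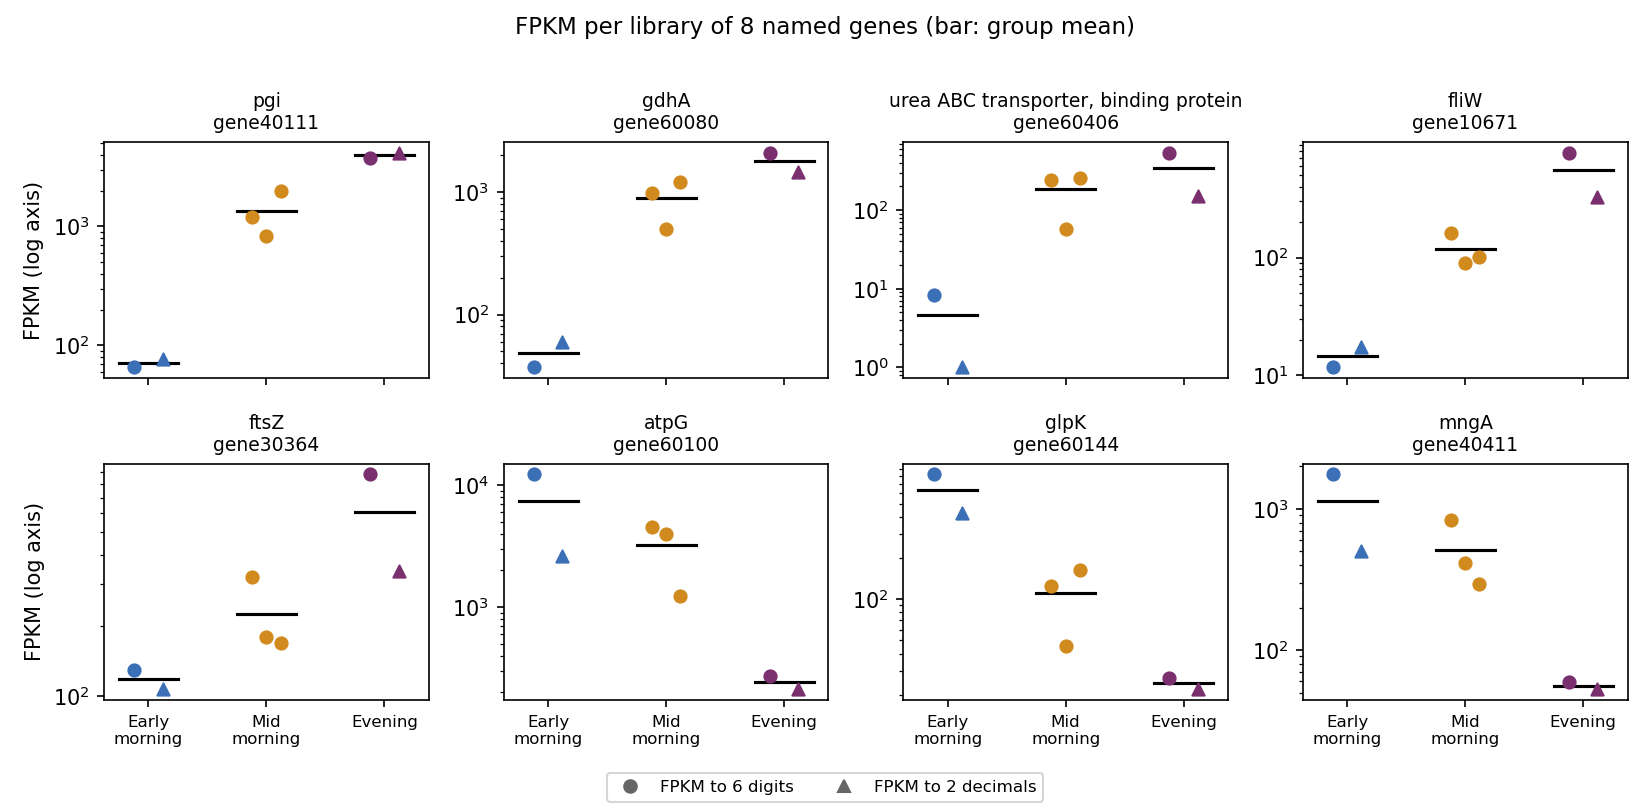
FPKM (log axis) of 8 named genes in each library, by time of day; bars are group means and shape gives the kind of FPKM column. pgi stands at a mean of 70.8 in the early morning, 1338 in the mid morning and 3974 in the evening, and glpK at 627, 111 and 24.2.

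Amino acid synthesis held the most called genes of the lists. Of its 54 genes, 30 rose, 1 fell and 23 did not pass (41 and 1 adjusted over the list alone), with a median log2 difference of 2.27 (camera adjusted p = 3.1e-10, 0.596 with an estimated correlation). Glutamate dehydrogenase (gdhA, gene60080), which binds ammonium into glutamate, rose from 48.2 ± 15.8 to 1789 ± 451 FPKM (n = 2 each), by 5.20 ± 0.58 (limma adjusted p = 0.0089), and the large subunit of glutamate synthase (gltA, gene60428) by 4.11 ± 0.57 (limma adjusted p = 0.0095). The member that fell, annotated as an NADPH glutamate synthase (gene10134), went from 203 ± 26.0 to 15.5 ± 3.59 FPKM (n = 2 each), a difference of −3.64 ± 0.49 (limma adjusted p = 0.0095). Proline synthesis (proC, gene30105) rose by 2.38 ± 0.47. Of 15 fatty acid and phospholipid genes, 10 rose and none fell (10 and 1 adjusted over the list alone), with a median of 2.51 (camera adjusted p = 0.0014, 0.596 with an estimated correlation), among them fabD (gene40143) by 3.36, fabF (gene40145) by 3.07 and the acetyl-CoA carboxylase subunit accA (gene40150) by 2.82.

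Of 50 ribosomal proteins, 14 rose, none fell and 36 did not pass (22 rose adjusted over the list alone), with a median of 1.59 (camera adjusted p = 1.0e-06, 0.596 with an estimated correlation). Those among the most abundant annotated genes did not pass: rpmH had −0.07, rpsU −0.21, rpmEA −1.45, rpsO −0.22, rpmB 0.56 and rpsR 0.33. As a share of the summed FPKM the list did not differ between the times (exact permutation p = 0.571). Protein S1 (gene70093) rose from 150 ± 26.7 to 1531 ± 75.8 FPKM (n = 2 each), by 3.36 ± 0.47 (limma adjusted p = 0.0098), rplJ (gene30306) by 2.62 and rpsG (gene40225) by 2.45. Of 29 translation factors and aminoacyl-tRNA synthetases, 13 rose and none fell (17 adjusted over the list alone), with a median of 1.81 (camera adjusted p = 1.7e-05, 0.596 with an estimated correlation), among them the synthetases ileS (gene40320) by 2.86, serS (gene40072) by 2.09 and glyQS (gene70125) by 1.90. Flagellar genes had 10 of 35 risen and none fallen (13 adjusted over the list alone), with a median of 1.45 (camera adjusted p = 0.00053, 0.596 with an estimated correlation). The assembly factor fliW (gene10671) rose by 5.05 ± 0.59, the export gate component flhA (gene10597) by 3.06 and FlhB (gene10598) by 3.12. The most abundant flagellin, fla (gene10576), stood at 1465 ± 607 and 3278 ± 548 FPKM (n = 2 each) and did not pass (1.22 ± 0.63, limma adjusted p = 0.192). Of 8 redox defence genes, 3 rose (also 3 adjusted over the list alone), with a median of 1.44 (camera adjusted p = 0.022, 0.596 with an estimated correlation): a rubredoxin (gene30374) by 4.32, the rubrerythrin rbr (gene70015) by 2.27 and a thioredoxin reductase (gene30271) by 1.76.

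All 14 ATP synthase genes had negative differences, 9 fell (10 adjusted over the list alone) and the median was −3.74 (camera adjusted p = 1.0e-06, 0.596 with an estimated correlation). The list joins 2 loci, gene60098 to gene60107, where 9 of 10 fell (median −3.90), and 4 genes between gene10461 and gene10465, where none passed (median −1.27). The gamma chain atpG (gene60100) fell from 7461 ± 6861 to 242 ± 43.7 FPKM (n = 2 each), a difference of −4.55 ± 0.91 (limma adjusted p = 0.021). Subunit delta (gene60102), atpF (gene60103), atpC (gene60098), atpA (gene60101) and the iota subunit (gene60107) fell as well, with −4.43, −4.27, −4.07, −4.00 and −3.62. The most abundant subunit, atpE2 (gene60104), had −3.70 ± 1.12 and did not pass (limma adjusted p = 0.057). Of 33 ABC sugar transport genes, 10 fell, 3 rose and 20 did not pass (19 and 4 adjusted over the list alone), with a median of −2.18 (camera adjusted p = 0.00012, 0.596 with an estimated correlation). A permease (gene40287) fell by 3.76 and msmX (gene70258) by 2.97, and an ATP-binding protein (gene40396) rose by 3.36. Of 20 PTS genes, 3 fell (1 adjusted over the list alone), with a median of −1.42 (camera adjusted p = 0.00053, 0.596 with an estimated correlation). mngA fell by 4.05 and a mannitol IIB subunit (gene60171) by 2.90, and an ascorbate IIC subunit (gene60170) did not pass (−2.38, limma adjusted p = 0.057). Of 10 sodium pumps and sodium-coupled carriers, 4 fell (6 adjusted over the list alone), with a median of −2.05 (camera adjusted p = 0.0072, 0.596 with an estimated correlation), among them a sodium:dicarboxylate symporter (gene40587, −3.25), a melibiose symporter (gene40382, −3.22) and a sodium:proton antiporter fragment (gene20106, −2.07). None of the 6 chemotaxis genes passed, over all genes or adjusted over the list alone, and the list as a whole stood lower (median −1.54, camera adjusted p = 0.030, 0.709 with an estimated correlation), with cheA (gene10593) at −1.45, gene10594 at −1.64 and cheD (gene10590) at −1.31.

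These 11 list calls rest on the preset correlation. With an estimated correlation none remained (adjusted p = 0.596 for 10 of them and 0.709 for chemotaxis), and with fry amino acid synthesis (adjusted p = 0.036) and translation factors (adjusted p = 0.0093) passed. In the fit to the 5 6-digit libraries, chosen after the values were seen, all 11 passed at the preset correlation, as did the nitrogen list (adjusted p = 0.026), and none at an estimated one (smallest adjusted p = 0.521). Without early morning replicate 1 redox defence and chemotaxis did not pass at the preset correlation, nor did redox defence without evening replicate 1 or chemotaxis without evening replicate 2. The 2-decimal kind holds only 1 early morning and 1 evening library, so the medians of the 6-digit and the 2-decimal pair are given as values. They were 2.40 and 2.16 for amino acid synthesis, 2.81 and 1.62 for fatty acids, 1.43 and 1.74 for ribosomal proteins, 1.63 and 1.44 for translation factors, 1.49 and 1.35 for the flagellum and 1.93 and 1.03 for redox defence. Of the lists that stood lower, they were −4.60 and −2.87 for ATP synthases, −2.38 and −1.50 for ABC sugar transport, −2.35 and −1.10 for the PTS, −2.31 and −1.65 for sodium carriers and −2.11 and −0.84 for chemotaxis.

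**Figure D4:**
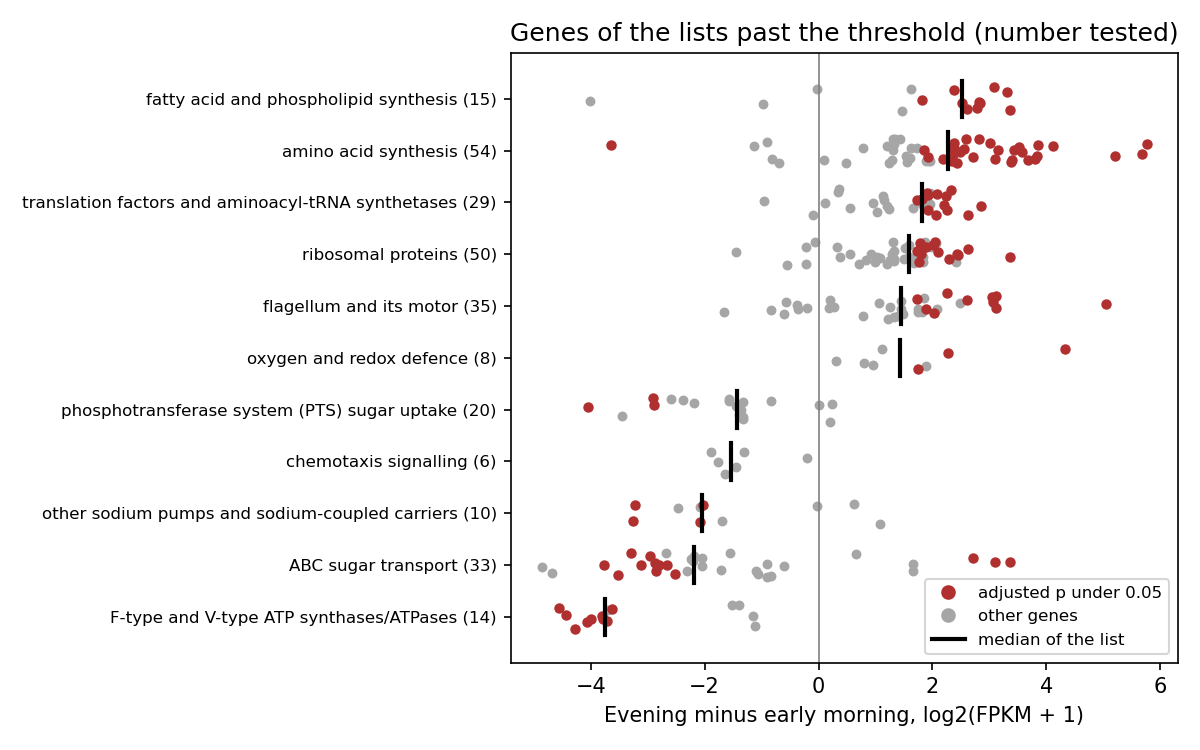
Evening minus early morning log2(FPKM + 1) difference of each tested gene in the 11 lists past the threshold; red points passed an adjusted p of 0.05, gray points did not, and black bars are list medians. Medians run from 2.51 (fatty acid and phospholipid synthesis) to −3.74 (ATP synthases).

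Sporulation genes went both ways. Of 30, 5 rose, 2 fell and 23 did not pass (also 5 and 2 adjusted over the list alone), and the list did not pass (median 0.26, camera adjusted p = 0.544). The regulator spoVT (gene30167) rose from 78.2 ± 7.64 to 1590 ± 1044 FPKM (n = 2 each), by 4.16 ± 0.68 (limma adjusted p = 0.014), and a GerA germination protein (gene10479) by 3.32. A YunB fragment (gene60064) fell by 2.29 and spoVG (gene10439) fell by 2.33 ± 0.65 (limma adjusted p = 0.044). The sporulation sigma factors and the master regulator did not pass: sigF (gene30238) had −0.56 ± 0.56, sigE (gene70133) −0.53 ± 0.49, sigG (gene70134) 1.27 ± 0.56, sigK (gene10658) 0.37 ± 0.61 and spo0A (gene70013) 0.20 ± 0.58 (limma adjusted p of 0.143 to 0.828). Of 16 cell division genes 3 rose and none fell (also 3 adjusted over the list alone, median 0.39, camera adjusted p = 0.405). These were mreB (gene30180), which shapes the cell, by 3.86, the chromosome segregation protein SMC (gene60288) by 2.24 and ftsZ (gene30364), which forms the division ring, from 118 ± 15.9 to 610 ± 383 FPKM (n = 2 each), by 2.21 ± 0.61 (limma adjusted p = 0.044). ftsZ lost its call with an equal sum, library weights, no trend, only the 2 groups in the fit, without both 2-decimal libraries and without any 1 library other than evening replicate 2 (limma adjusted p of 0.021 to 0.232 over all alternatives). The replication initiator dnaA (gene30123) did not pass (−0.68 ± 0.50, limma adjusted p = 0.347).

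Other lists held called genes without passing as a whole. Of 35 glycoside hydrolases, which split sugar polymers, 10 rose and 3 fell (13 and 7 adjusted over the list alone, median 1.19, camera adjusted p = 0.206), with licH (gene30292) up by 5.02, lacZ (gene10650) by 3.46 and a beta-glucosidase (gene70083) by 2.41. The 129 genes with the authors' own glycoside hydrolase label, chosen after the values were seen, had a median of the other sign (−0.43, 22 risen and 14 fallen, camera adjusted p = 0.318). Glycolysis had 2 of 13 genes risen, pgi and ppdK (gene70126, 2.53), while apgM (gene40004) did not pass (median 0.07, camera adjusted p = 0.549). Among 14 genes of pyruvate conversion and fermentation 3 rose and 2 fell (camera adjusted p = 0.997, median −0.19 and mean 0.19), with an alcohol dehydrogenase (gene10070) up by 2.71, leuB (gene40279), a leucine synthesis enzyme taken in by its product name, up by 3.84, and an oxaloacetate decarboxylase (gene30465) down with −2.76. Peptidoglycan synthesis had dacF (gene40454) risen by 5.38 as its sole call of 18 (camera adjusted p = 0.361), and uppS and uppP did not pass. Of 16 chaperones and proteases, groEL (gene40502) rose by 2.02, and dnaK (gene60331) and dnaJ (gene60332) did not pass (camera adjusted p = 0.534). Of 11 RNA polymerase and sigma factor genes, rpoA (gene60248) rose by 1.74 and nusG (gene30302) by 1.83, and rpoC (gene30310) did not pass (camera adjusted p = 0.534). Of 18 replication genes a topoisomerase IV subunit (gene30418) rose by 2.44 and a single-stranded DNA-binding protein (gene70067) fell by 2.65, with dnaG (gene70127) not past (camera adjusted p = 0.808). Of 20 DNA repair genes ung (gene30443) and recG (gene40365) fell by 2.82 and 1.75, and a MutT protein (gene40505) did not pass (camera adjusted p = 0.808, median 0.14 and mean −0.0027). Of 20 nucleotide synthesis genes 1 rose, adenylosuccinate lyase (gene60169, 2.57), and 2 fell, purC (gene70072, −1.88) and gene70074, a purine synthesis enzyme (−1.85; camera adjusted p = 0.915). Adjusted over the list alone, 2 glycolysis, 3 risen and 2 fallen fermentation, 1 peptidoglycan, 2 RNA polymerase, and 1 risen and 2 fallen nucleotide synthesis genes passed, with 0 chaperone, 0 replication and 1 fallen DNA repair gene.

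Of 7 genes in the nitrogen list, which caught urease genes and the 2-oxoacid oxidoreductase nifJ, none passed, over all genes or adjusted over the list alone (median 1.15, camera adjusted p = 0.189). The stable RNA list caught 6 tRNA-modifying enzymes, of which tadA (gene20070) rose by 3.95 (also past adjusted over the list alone) and tcdA (gene20098) and mnmA (gene10361) did not pass (camera adjusted p = 0.349). The mobile element list held 2 genes and was not tested. Its group II intron gene (gene10364) had 6.90 ± 3.60 and its integrase (gene10583) 0.48 ± 0.77, and neither passed (limma adjusted p = 0.195 and 0.682). No product matched the Rnf complex pattern.

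Between early and mid morning 10 genes rose and none fell (limma, 527 at an unadjusted p under 0.05). Groups did not overlap for the 10, as for 36.7% of all genes, where chance gives 20%. Among the annotated genes of these 10, the largest rise was that of the CE14 de-N-acetylase (gene30290), from 2.71 ± 1.06 (n = 2) to 99.1 ± 25.7 FPKM (n = 3), by 4.75 ± 0.49 (limma adjusted p = 0.034). A peptide ABC transporter ATPase (gene30287) rose by 4.22, gdhA by 4.14, pgi by 4.14, a nucleotidyltransferase (gene40096) by 3.77, a pyridine nucleotide-disulfide oxidoreductase (gene30294) by 3.74 and the 6-phospho-beta-glucosidase licH (gene30292) by 3.68, and the other 3 were of unknown function. The count was 0 without any 1 library, with a pseudocount of 10, median-of-ratios scaling, no trend, only the 2 groups in the fit or a term for the kind of column, and 2 with an equal sum. It was 19 with a pseudocount of 0.1 or a mean of at least 10 FPKM, 21 (18 higher, 3 lower) with quantile normalization and 83 (73 higher, 10 lower) with genes of at least 600 nt.

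As lists, 6 stood higher in the mid morning and 2 lower, and with an estimated correlation none of the 8 remained (adjusted p of 0.667 to 0.694). Higher were amino acid synthesis (median 1.27, camera adjusted p = 1.6e-10), and, in the same order of values, ribosomal proteins (1.45, 1.0e-09), translation factors (1.27, 3.0e-06), fatty acid synthesis (1.52, 0.0012), glycoside hydrolases (1.14, 0.0041) and the nitrogen list (1.69, 0.0033). The glycoside hydrolases here are 35 matched by name, and the 129 genes with the authors' own label, a set chosen after the values were seen, had a median of 0.28 and did not pass (camera adjusted p = 0.491). With ureE (gene60416) at 2.30 ± 0.52, ureA (gene60413) at 1.70 and ureF (gene60417) at 1.69, no nitrogen gene passed over all genes, and 5 of 7 did when adjusted over the list alone. Lower were ABC sugar transport (−0.65, 0.0033) and the PTS (−0.46, 0.0033). Without early morning replicate 1 these 2 and the nitrogen list did not pass, which left 5 lists higher and 0 lower. Adjusted over the list alone, 24 amino acid synthesis genes, 29 ribosomal proteins and 11 translation factors passed, all higher, and 1, 0 and 0 did over all genes. In these comparisons all 3 mid morning libraries have 6-digit columns and 1 of the 2 early morning libraries has not, and short genes differ between the kinds. Ribosomal proteins held 22.6% and 11.2% of the summed FPKM in the early morning libraries and 20.5% to 23.8% in the mid morning ones. Without early morning replicate 2, the 2-decimal library, the list median of ribosomal proteins was 1.03 (camera adjusted p = 5.0e-06, 0.590 with an estimated correlation). Of the lists, fry passed translation factors (adjusted p = 0.018).

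Between mid morning and evening no gene passed (limma, 521 at an unadjusted p under 0.05), and the groups did not overlap for 41.2% of genes, where chance gives 20%. With library weights 247 genes passed (77 higher, 170 lower), and without evening replicate 2 there was 1. The smallest unadjusted p among annotated genes belonged to the collagen repeat fragment (gene20024, 3.83), proC (1.78), protein S1 (1.72), fliW (2.14) and secA (gene10208, 1.90) on the higher side. On the lower side it belonged to gene10134 (−3.12), a cysteine-rich protein (gene10133, −3.23), ydjX (gene10132, −3.18), an acetyltransferase (gene30379, −2.24) and a sulfurtransferase (gene10135, −2.72), with a limma adjusted p of 0.158 for each of the 10. With an estimated correlation none of the 9 lists that follow remained (adjusted p of 0.647 to 0.740). As lists, amino acid synthesis (median 0.88, camera adjusted p = 2.5e-05), the flagellum (median 0.82, camera adjusted p = 0.00031) and, in the same order of values, fatty acid synthesis (1.04, 0.027), redox defence (0.89, 0.027) and translation factors (0.42, 0.045) stood higher. ATP synthases (−3.16, 1.2e-08), ABC sugar transport (−1.29, 0.0028), sodium carriers (−1.29, 0.017) and the PTS (−0.65, 0.027) stood lower. Adjusted over the list alone, 12 of 14 ATP synthase genes passed, all lower. At the preset correlation fatty acid synthesis, the PTS and translation factors did not pass without mid morning replicate 3, nor did these 3 and redox defence without evening replicate 1, nor translation factors without mid morning replicate 1 or evening replicate 2. Of the lists, fry passed none (smallest adjusted p = 0.233).

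As shares of the summed FPKM, amino acid synthesis genes held 0.404 ± 0.235% in the early morning (n = 2), 0.747 ± 0.160% in the mid morning (n = 3) and 1.41 ± 0.264% in the evening (n = 2; exact permutation p = 0.0095, the smallest possible). ATP synthase genes held 2.96 ± 0.953%, 1.78 ± 0.953% and 0.256 ± 0.0580% (exact permutation p = 0.095). ABC sugar transport held 1.31 ± 0.398%, 0.617 ± 0.193% and 0.242 ± 0.0782% (exact permutation p = 0.019), and sporulation genes 4.42 ± 0.405%, 3.49 ± 0.555% and 2.50 ± 0.779% (exact permutation p = 0.038). Of the sporulation share, spoIIID (gene10378) alone made up 43.8% to 70.7% in each library, and without it the share was 1.91 ± 0.352%, 1.04 ± 0.149% and 1.40 ± 0.445% (exact permutation p = 0.095). By gene, 17 of the 30 genes had positive evening minus early morning differences. Ribosomal proteins held 22.6% and 11.2% in the early morning, 20.5% to 23.8% in the mid morning and 21.6% and 17.6% in the evening (exact permutation p = 0.571). The 35 glycoside hydrolases held 1.16 ± 0.203%, 1.09 ± 0.121% and 0.870 ± 0.0613% (exact permutation p = 0.210). Of the 24 lists, 7 had an unadjusted exact p under 0.05 and none passed after adjustment (smallest adjusted p = 0.091). Since the smallest possible exact permutation p is 0.0095, several lists would have to reach it for any to pass, so this test could hardly pass a list.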

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

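The alternatives that use a term for the kind of FPKM column, leave out both 2-decimal libraries or keep genes of at least 600 nt were chosen after the values were seen. All 536 genes called between early morning and evening, and all 10 between early and mid morning, kept their direction in every alternative in which they were tested. The groups of each of these genes did not overlap, so fits that left out libraries could not turn a direction. The other scalings could have done so. The count of genes over the 3 times (170) was 126 to 215 in 10 alternatives, 272 with median-of-ratios scaling, 325 with quantile normalization, 371 with genes of at least 600 nt (fewer genes tested) and 0 without both 2-decimal libraries (fewer samples). Its range was 0 to 168 when 1 library was left out. For mid morning against early morning (10 genes) it was 0 with a pseudocount of 10, median-of-ratios scaling, no trend, only the 2 groups in the fit, the kind of column as a term (with or without median-of-ratios scaling) and without both 2-decimal libraries. It was 2 with an equal sum, 19 with a pseudocount of 0.1 and with a mean of at least 10 FPKM, 21 with quantile normalization, 83 with genes of at least 600 nt, and 0 without each library. For evening against early morning (536) it was 355 with library weights, 59 with only the 2 groups in the fit, 0 without both 2-decimal libraries (922 at an unadjusted p under 0.05). It was 398 to 738 in the other alternatives on all 7 libraries, and 0 to 477 when 1 library was left out, with more lower (215) than higher (154) genes without early morning replicate 2. With the kind of column as a term, 632 genes were called and 512 of the 536 were among them. For evening against mid morning (0) it was 247 with library weights and 0 to 1 when 1 library was left out. The fits without 1 library or without a kind of column leave groups with 1 sample, which is assumed to vary like the others. Median-of-ratios scaling moved the median log2 difference of all genes by −0.26, −0.13 and 0.13 in the 3 comparisons (in the order mid against early morning, evening against early morning, evening against mid morning). An equal sum and quantile normalization moved the first 2 by −0.32 and −0.24 and by −0.24 and −0.21. Lists past the threshold were 8, 11 and 9, fell to 0, 0 and 0 with an estimated correlation and to 1, 2 and 0 with fry, and ranged over 5 to 12, 9 to 11 and 6 to 10 when 1 library was left out (5 higher and 0 lower for mid against early morning without early morning replicate 1). No list passed as a share of summed FPKM in any alternative. Without a mid morning library none could, since 3 groups of equal size leave a smallest possible exact p above 0.05. Of the 15 most abundant genes 14 or 15 stayed, in settings that all kept most of the 6-digit columns. The cause of these changes was not tested, also where fewer genes or samples are named beside a count.

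Of 3041 values of named genes under alternatives, 2411 kept their side of the threshold, 551 no longer passed, 42 passed only there and 37 changed sign. The sign changes were all in evening against early morning, in genes that had not passed. Every named gene was followed in that comparison, but the other comparisons followed only the genes chosen for them, so fewer could change there. gene40119 had −0.0204 with median-of-ratios scaling, also with the kind term, −0.11 with an equal sum, −0.22 without both 2-decimal libraries, and −0.98 to 1.21 when 1 library was left out. gapA (gene40302) had −0.0665 with median-of-ratios scaling, also with the kind term, −0.16 with an equal sum, −0.15 with quantile normalization, −0.48 without both 2-decimal libraries, and −0.45 to 0.59 when 1 library was left out. spo0A (gene70013) had −0.0249 with an equal sum, −0.13 without both 2-decimal libraries and −0.38 to 0.79 when 1 library was left out. Without both 2-decimal libraries rpmB (gene70167) had −0.60 and rpsR (gene60044) −0.64, and their ranges when 1 library was left out were −1.44 to 2.55 and −1.03 to 1.69. The other such ranges were −2.66 to 2.53 for rpmH (gene30122), −1.37 to 0.94 for rpsU (gene10179), −2.09 to 0.18 for spoIIID (gene10378), −2.88 to 0.83 for SCIFF (gene10333), and −3.22 to 0.32 for rpmEA (gene30040). They were −1.31 to 0.87 for rpsO (gene50008), −1.95 to 0.71 for pflB (gene10573), −0.17 to 1.04 for hbs (gene30168), −1.18 to 0.0608 for sigF (gene30238) and −0.0347 to 0.999 for the integrase (gene10583). No paired analysis was possible because the labels number no replicates. Depth could be read for 2 libraries only, so no value was weighed by it.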

Other observations

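Of the tests in this part, the splits of the libraries were planned before the data were examined, and the tests of the column kind, scaling, extraction reagent, gene length and identifier order, the run and cluster counts with the genes named from them, and the carbohydrate-active enzyme lists were chosen after the values were seen. A neighbourhood of 8 short genes of unknown function, gene70315 to gene70322 (up to 375 nt), came to hold a large part of the measured transcriptome. Its share of the summed FPKM was 0.759 ± 0.0047% in the early morning (SD, n = 2), 3.93 ± 3.27% in the mid morning (n = 3) and 14.1 ± 2.29% in the evening (n = 2), with 15.7% in the 6-digit and 12.5% in the 2-decimal evening library. The mid morning libraries had 3.11%, 1.15% and 7.53%, and their mean without mid morning replicate 3 was 2.13%. Of the 8 genes, 5 rose between early morning and evening (limma), among them gene70317 by 4.56 ± 0.98 (adjusted p = 0.025) and gene70321 by 4.48 ± 1.08 (adjusted p = 0.031). gene70318 (69 nt) was listed at 0 in 4 of the 5 6-digit libraries and stood at 29632 FPKM in the 2-decimal evening library. These genes are of the lengths whose levels differed between the kinds of column.

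The sets of neighbours named next were taken from runs of genes called in 1 direction, so that their members share a direction by choice. Between early morning and evening, 7 genes of leucine, isoleucine and valine synthesis (gene40276 to gene40282) rose with a median of 3.44, and 8 with neighbouring identifiers that include the tryptophan genes trpA to trpE (gene40303 to gene40310) with 2.81. A set of 9 genes with legG and legI, which make the surface sugar legionaminic acid (gene40092 to gene40100), rose with a median of 4.41, and 5 around the anaerobic sulfite reductase asrABC (gene10243 to gene10247) with 3.03. The riboflavin genes ribH, ribAB and ribE and 2 acetyltransferases (gene30378 to gene30382) fell with a median of −3.02, and a set with 2 glutaconyl-CoA decarboxylase subunits (gene30464 to gene30469) with −2.47. One glycerol kinase (gene60144) fell by 4.57 ± 0.69, and the other (gene40574) rose by 3.72 ± 0.78 (limma adjusted p = 0.024). With the authors' own family labels, 22 of 129 glycoside hydrolases rose and 14 fell (23 and 17 adjusted over the list alone, median −0.43, camera adjusted p = 0.318). In the same comparison 5 of 28 carbohydrate esterases rose and 1 fell (camera adjusted p = 0.226), none of 8 polysaccharide lyases rose and 1 fell (camera adjusted p = 0.226), and 2 of 16 glycosyltransferases rose (camera adjusted p = 0.291). None of these 4 lists passed in any comparison (smallest adjusted p with an estimated correlation 0.644).

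The 7 libraries were split into groups of 2, 3 and 2 in 100 ways (of 105 possible). Of these, 2 gave at least the 170 genes of the real split, itself included. The highest other split gave 197 and put mid morning replicate 3 with the evening libraries in place of the other mid morning ones. It kept the early morning pair, so the splits do not separate the time of day from these 2 fish. In all, 24 splits gave any gene, and the 10 with both 2-decimal libraries in 1 group of 2 gave up to 67. The libraries thus differed by more than the time of day. Such a count was rare among splits (under 0.05), but chance is not excluded by it. The early morning and the evening each hold 1 library of each kind, so an additive effect of the kind cancels in their difference. Across genes, the evening minus early morning differences of the 2 same-kind pairs, which share no library, correlated with r = 0.72. This was the highest of 10 such differences between 6-digit libraries (next 0.60). The pairs thus changed alike, but this r holds no such effect and cannot speak for or against it. It does not cover the comparisons with mid morning, where the kinds are not balanced. Median-of-ratios scaling called 653 genes, and 280 were called without the Trizol library, so neither explains the whole change. Across all libraries the 536 genes had a median absolute log2 difference of 2.86 (median SE 0.62). It was 2.63 (0.76) without evening replicate 1 and 3.31 (0.79) without both 2-decimal libraries, the fits in which the calls ended. Without evening replicate 2 it was 3.10 (0.77) and calls remained, at the same 3 residual degrees of freedom as without evening replicate 1. The difference was smaller without evening replicate 1, and the prior degrees of freedom also differed (3.15, against 3.63 without evening replicate 2). These fits do not settle why the calls ended there. That all 536 kept their direction was fixed beforehand, since their groups did not overlap. A change with the time of day is a hypothesis that may hold, and differences between the few fish other than the hour of catch (diet, site, date or the size of the fish) stay open and untested, since each group holds 2 or 3 fish.

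The excess of short genes in 5 columns may come from an effective length, shortened by the fragment size, in place of the full coding length. The excess of genes of up to 300 nt over genes of over 1000 nt (median log2) between the 6-digit and the 2-decimal library of 1 time of day was 1.002 and 0.68, against at most 0.128 in size among the 10 pairs of 6-digit libraries. Mixed pairs of different times of day had 0.448 to 0.861 with the early morning 2-decimal library and 0.113 to 0.463 with the evening one, and the 2-decimal pair differed by 0.354, so the excess also depended on the library and its lowest value lay within the range of 6-digit pairs. Besides, 34 genes with a median of 162 nt were listed at 0 in all 5 6-digit libraries and above 0 in both others. The reverse count could only be 0, since evening replicate 2 listed just 3 genes at 0, those at 0 in all libraries. A difference in library preparation between these libraries would give a like excess and stays open, and no biological explanation was tested.

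Called genes often had consecutive identifiers. Runs of at least 5 genes called in 1 direction between early morning and evening held 117 genes (21.8% of 536) in 17 runs, 10 higher and 7 lower, against a median of 0 and at most 15 genes in 1000 shuffles of the calls, so a chance order is excluded. The longest, gene30282 to gene30294 (13 genes, median 5.12), holds a peptide transporter, the etherase murQ, the CE14 de-N-acetylase and licH. Transcription of neighbouring genes as 1 unit is a candidate explanation that was not tested, since strand and coordinates were not used here, and reads assigned to more than 1 gene of a neighbourhood stay open as well.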
